A study of Mus musculus with 5 samples.

How the data were processed

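Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on C2C12 cells, a mouse line of muscle precursor cells (strain C3H) that divide as myoblasts in rich medium and fuse into myotubes once the serum is lowered. DNA bound by Spt6 or by KDM6A was isolated with an antibody from sonicated nuclei, made into libraries with the NuGEN Ovation SP Ultralow system and sequenced on an Illumina HiSeq. The 5 libraries form 5 groups of 1 library each: Spt6 in myoblasts, Spt6 in myotubes after 48 hours of differentiation, KDM6A in myoblasts, KDM6A in myotubes after 48 hours, and KDM6A in myoblasts in which KDM6A was knocked down. No group has a replicate, so no p-value is given, and every ratio compares libraries and not conditions.

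For each library the authors deposited the positions of the aligned reads and a list of enriched regions. The genome build is mm9 and the regions were called with SICER, both per the submitters' processing notes. The aligner, its settings, the SICER window, gap and threshold, and whether a control library was used are not given in the sources used here. The deposited region lists give a first and a last position only, with no height, fold enrichment or q-value. Regions start on a 200 bp grid and neighbouring regions lie at least 800 bp apart. The deposited read files of the Spt6 libraries also hold a score per read, a whole number of unstated meaning that entered no comparison, and a string of matches and mismatches along the read. In the KDM6A files each combination of position and strand occurs once, so repeated reads were removed before deposit, whereas 3.38% of the Spt6 myoblast reads and 4.48% of the Spt6 myotube reads repeat a position and strand. The Spt6 myoblast library mixes 9969371 reads of 32 bases with 4269871 reads of 99 bases, and the other 4 libraries hold reads of 50 bases.

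The libraries hold 14239242 (Spt6 myoblast), 22997891 (Spt6 myotube), 19255866 (KDM6A myoblast), 22276612 (KDM6A myotube) and 37735692 (KDM6A knockdown) reads. A single read per position and strand was kept and its start was moved 75 bp toward the centre of the fragment. Only reads on the 19 autosomes and chromosome X were counted. For each comparison the lists of both libraries were merged, reads were counted in each merged region, and counts were scaled to all reads used. Densities computed here are given as RPKM, with the reads used as the library total. Regions with at least 30 reads in the pair of libraries, after scaling to the smaller library, were compared. The log2 ratio was taken after 5 reads were added to each scaled count. Each ratio has an exact conditional binomial (Clopper-Pearson) 95% interval, and a region is called higher or lower when that interval lies wholly beyond a 1.5-fold change. Shares have Wilson 95% intervals. These intervals cover counting error only. Intervals of a median over regions come from the ranks of its values. They treat regions as independent, so they are too narrow where neighbouring regions change together.

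Overlap means at least 1 bp in common, and its chance level is the mean over 1000 random circular shifts of the regions within each chromosome. Similarity of libraries is given as Pearson and Spearman correlations of read counts over 5 kb windows, which are not independent replicates. Enrichment is given as density over flanks, the reads per kb in a region divided by the reads per kb in 20 kb on either side, starting 2 kb away and outside all called regions and nearly empty windows. A value needed at least 10 kb of such flank and 20 reads in it. This measure was chosen after seeing the data. A 1 kb window is called nearly empty when it holds at most 2 knockdown reads, and a region is called clear when less than 20% of its length lies in such windows. This definition was also added after the data were seen, because windows with many KDM6A reads and no knockdown reads point to a different treatment of reads with several genomic matches among the files. A stricter set, added later, holds the clear regions whose density is at least 0.8 times that of their flanks in both Spt6 libraries, and is called the regions with Spt6 background.

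Per comparison, the 5 regions with the largest and the 5 with the smallest ratio are named, ranked by the bound of the interval nearest to a ratio of 1, together with the densest regions of each list. This rule, the overlaps, ratios and correlations with their intervals and the first group of alternative settings were fixed before the data were examined. Density over the flanks was not. Joint change of Spt6 and KDM6A was measured over the merged regions of the 4 lists other than the knockdown list. Groups of regions were set beside 10000 random groups of the same size matched on read density in 20 bins, or beside 1000 where the group held over 1000 regions. The joint change analysis was added after the data were seen.

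The counting and the intervals were tested on Poisson counts simulated from the pooled rates of both libraries, with 200 changed regions. These regions were raised in the first-named library and picked among those above a minimum of expected reads. Neither losses nor a spread beyond Poisson were simulated, so the shares below do not describe calls of lower regions. For Spt6, myotube against myoblast, 52% of the regions changed 2-fold were called among 27235 regions, and 100% of those changed 4-fold among 27237. For KDM6A, myotube against myoblast, 49.5% of the regions changed 2-fold were called among 34806, and for knockdown against control 41% among 35389. At 4-fold, 100% were called for both KDM6A comparisons, among 34799 and 35394 regions.

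Alternatives fixed in advance changed the scaling, the treatment of repeated reads, the reads added, the read minimum, the shift of the reads, the depth, the overlap that counts as shared and the size of the region lists. Alternatives added after seeing the data were scaling to the flanks, the clear regions, the regions with Spt6 background, either read length of the Spt6 myoblast library alone, joint change without a 1 Mb cluster on chromosome 2, and calling of all 5 libraries by 1 method at equal depth. That method counts reads in 200 bp windows, joins windows above a Poisson threshold (p of 0.2 over 80% of the genome) across gaps of up to 600 bp, keeps joined windows above the score that 100 stretches of a random genome pass, and uses no control library. Positions are counted from 1 in mm9. An annotation of that build was not used here, so regions carry positions and no gene names, and the intended ratios over genes, the gene lists and the markers of other cell types were not run. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.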

Results

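Binding of Spt6 and of KDM6A across the genome was measured by ChIP-seq in dividing C2C12 myoblasts and in myotubes after 48 hours of differentiation. Spt6 is a histone chaperone and elongation factor that travels with RNA polymerase II, and KDM6A (also called UTX) is a demethylase that removes methyl groups from lysine 27 of histone H3. The 5 libraries, 1 per group and without replicates, held between 14239242 (Spt6 myoblast) and 37735692 (KDM6A knockdown) aligned reads. After 1 read was kept per position and strand, 13754270 reads were used for Spt6 in myoblasts, 21963412 for Spt6 in myotubes, 19237050 for KDM6A in myoblasts, 22251070 for KDM6A in myotubes and 37721555 for the knockdown. Of the Spt6 myotube reads 34.8% matched the genome without a mismatch, against 89.6% and 78.0% of the reads of 32 and 99 bases that make up the Spt6 myoblast library. Regions are given by their mm9 positions, without gene names, since no annotation of that build was used here.

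The authors' list for Spt6 in myoblasts held 24842 regions that covered 182 Mb, and 27.6% of the reads of that library lay in them (Wilson 95% interval 27.56% to 27.60%). In myotubes the Spt6 list held 16536 regions over 60.1 Mb with 7.71% of the reads (7.69% to 7.72%). KDM6A had 33968 regions over 118 Mb with 16.2% of the reads in myoblasts (16.17% to 16.21%), and 20905 regions over 89.6 Mb with 11.3% of the reads in myotubes (11.29% to 11.32%). After the knockdown the KDM6A list shrank to 4255 regions over 28.9 Mb with 2.44% of the reads (2.44% to 2.45%), although that library was the deepest. The median region was 5000 bp wide for Spt6 in myoblasts and 2800 bp in myotubes, and 2600 bp for KDM6A in myoblasts and 3400 bp in myotubes. With 1 calling method at an equal depth of about 13754270 reads these widths were 5400, 5200, 3800 and 3600 bp. The stages then differed little in width for either protein, so neither difference in the authors' lists was kept. The lower number and covered length in myotubes held with this method for both proteins, with 171.7 Mb against 61.7 Mb for Spt6 and 100.4 Mb against 63.5 Mb for KDM6A. Both myotube libraries were the deeper ones, so equal depth alone was unlikely to remove these differences.

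**Figure D1:**
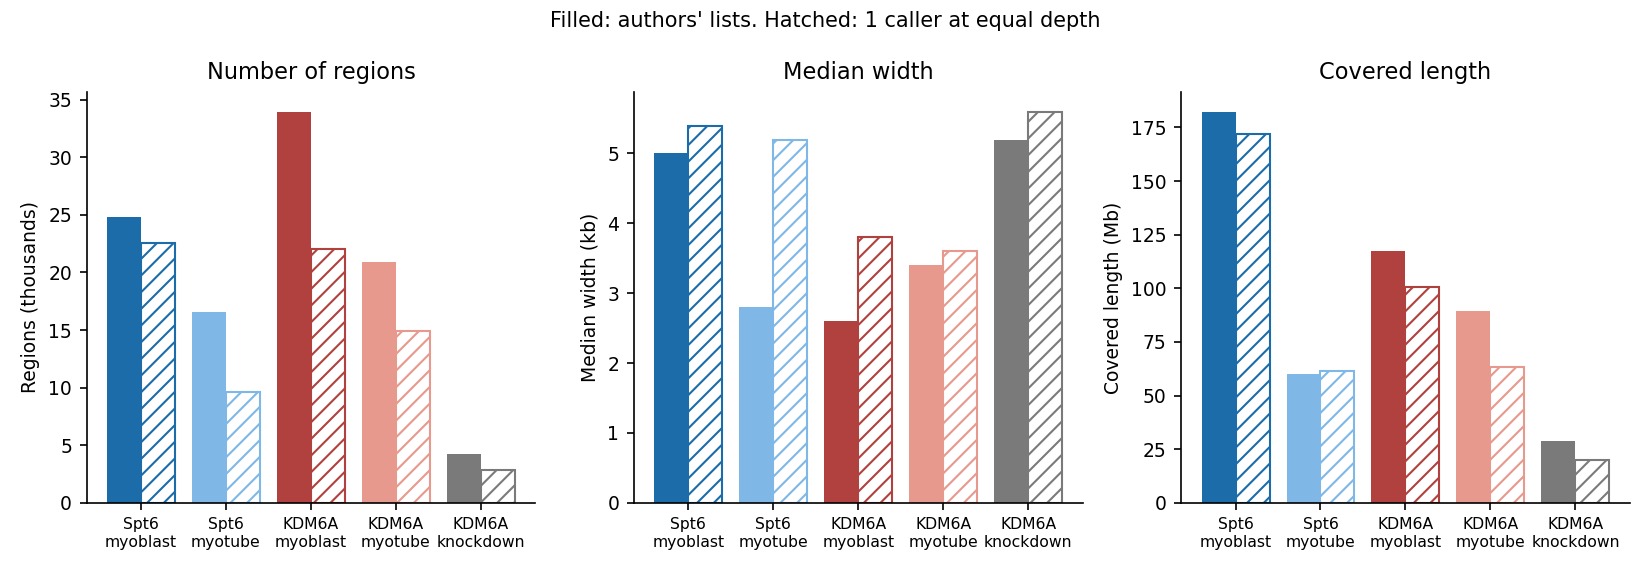
Number of regions (axis in units of 1000), median region width (kb) and covered length (Mb) for each of the 5 libraries, as filled bars for the authors' lists and hatched bars for 1 calling method at equal depth. The Spt6 myoblast library covers the most genome (182 Mb in the authors' list) and the KDM6A knockdown the least (28.9 Mb).

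The question of the first comparison is where Spt6 binding differs between dividing myoblasts and myotubes. Spt6 was lower in myotubes over far more regions than it was higher: of 27264 regions, 5901 were lower and 196 higher beyond 1.5-fold, with a median log2 ratio of -0.68. Ranked by the bound of the interval nearest to 1, the largest rise lay on chromosome 1 at 136185801 to 136193800, where Spt6 was 11.1 times higher in myotubes (95% interval 8.78 to 14.2, 1327 reads against 75, with reads given unscaled). The largest loss lay on chromosome 4 at 135693801 to 135705000, where Spt6 was 15.8 times lower in myotubes (13.2 to 18.9, 141 reads against 1392). Some of the gained regions lay close together: 33 of the 47 regions tested in 1 Mb of chromosome 2 were higher in myotubes, and these lay between 76535001 and 76997200. No chance level for such grouping was computed.

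Other gained regions were on chromosome 2 at 180119601 to 180141000 (10.6 times higher, 8.71 to 12.9), on chromosome 1 at 136087201 to 136101000 (9.35 times, 7.70 to 11.5), on chromosome 2 at 113870601 to 113878800 (6.11 times, 4.35 to 8.82) and inside the chromosome 2 cluster at 76751801 to 76760000 (5.29 times, 3.96 to 7.19). In the myoblast library the first of these had a density of 0.977 times that of its flanks and in the myotube library 7.53 times. The pair on chromosome 1 belonged to a further cluster, from 136056401 to 136222400, in which 7 of 31 regions were higher. Clusters of 6 higher regions were also found on chromosome 3 between 55150601 and 55332400, among 36 tested, and on chromosome 8 between 15058401 and 15137000, among 12 tested. Among the regions with the largest loss, a pair was on chromosome 13, at 21867801 to 21873200 (9.40 times lower in myotubes, 7.96 to 11.2) and at 23851001 to 23857200 (9.28 times, 7.89 to 10.98). The others were on chromosome 3 at 96051001 to 96053600 (9.79 times lower, 7.47 to 13.0) and on chromosome 2 at 117935601 to 117958400 (8.11 times, 7.39 to 8.91). In myoblasts the chromosome 13 pair had Spt6 densities of 36.0 and 46.2 times their flanks. The 1 Mb stretch with the most losses was on chromosome 5, between 136105001 and 136999600, where 29 of 52 regions were lower. All 10 named regions kept their direction when the myoblast library was restricted to its reads of 32 or of 99 bases. In the regions of the Spt6 myoblast list the median density over flanks was 2.23 for the myoblast library (2.22 to 2.24) and 1.39 for the myotube library (1.38 to 1.39), and in those of the Spt6 myotube list it was 2.60 (2.56 to 2.64) and 2.19 (2.17 to 2.202). The counts of higher and lower regions depended on the scaling: scaling by the median of ratios, which puts the median log2 ratio at 0.00 and so moves it by 0.68, gave 1549 higher and 449 lower regions. Within the myoblast library, the reads of 99 bases against those of 32 bases already gave 1600 higher and 13 lower regions of 19236, and 33 higher and 2170 lower regions were called with all reads and with either read length.

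**Figure D2:**
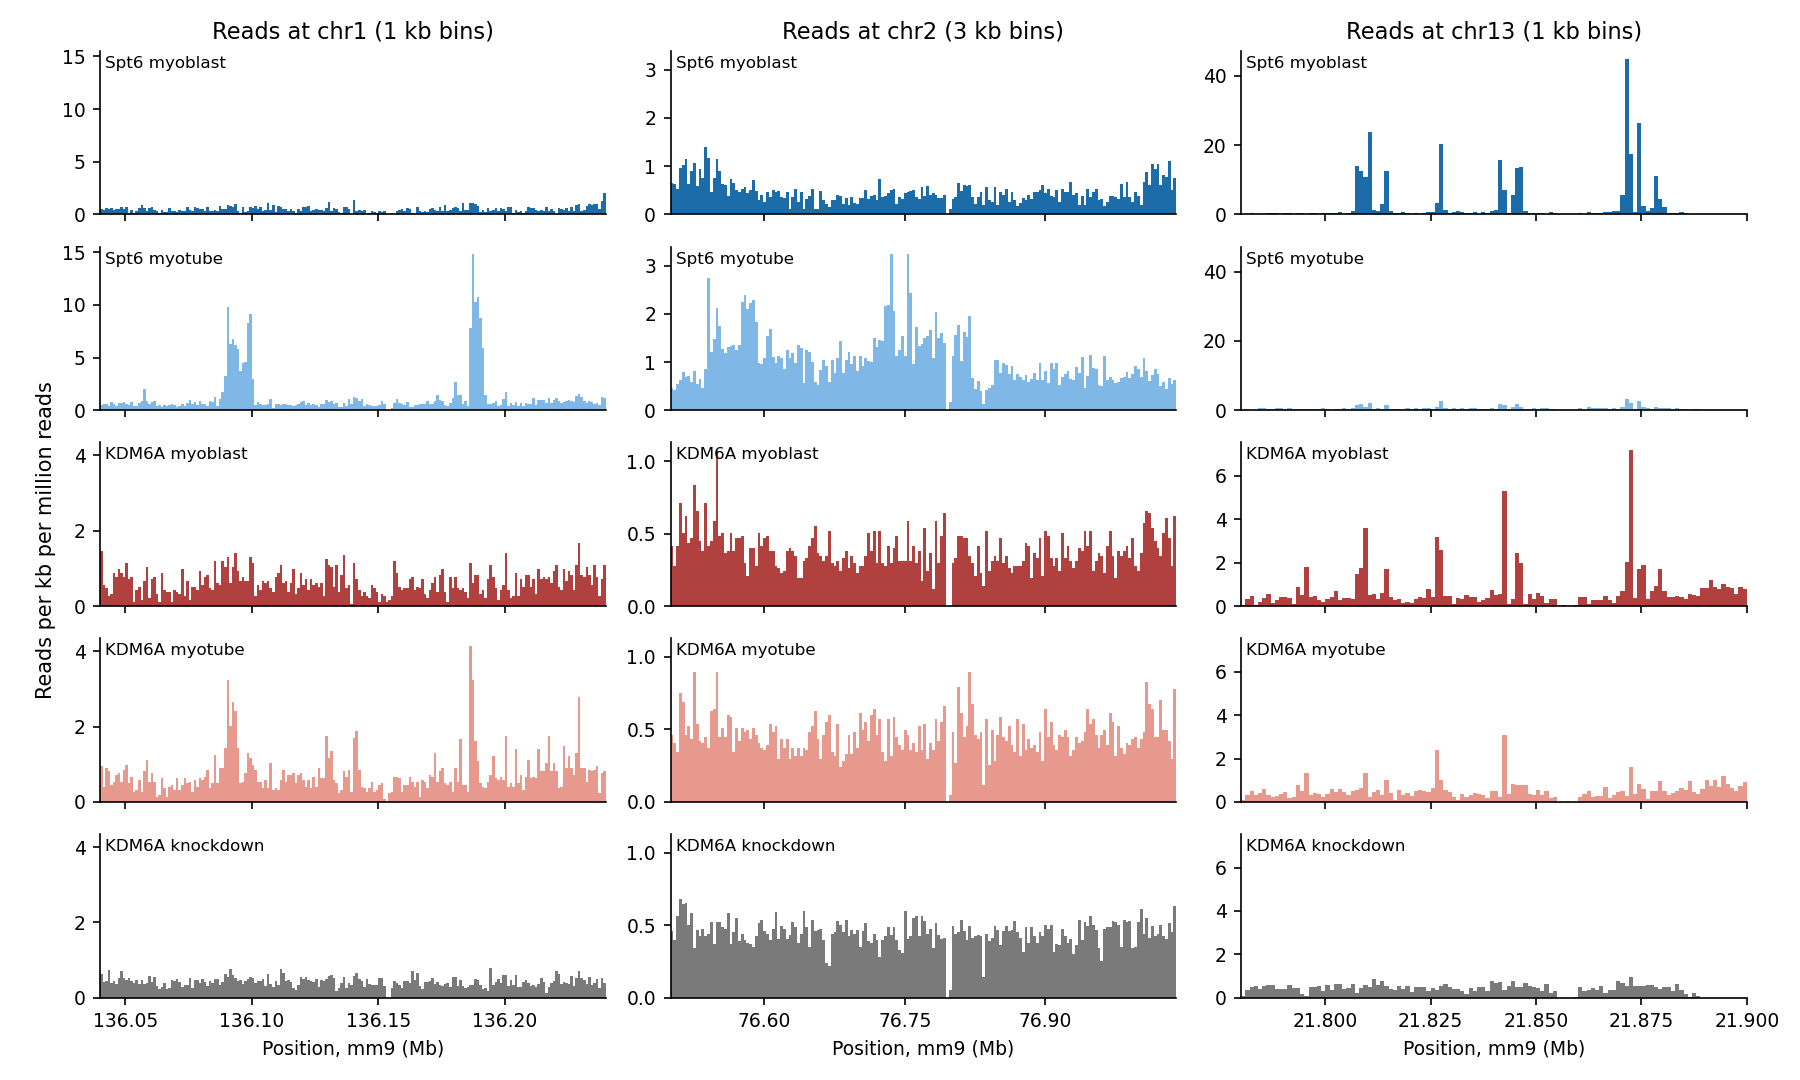
Read density (RPKM, reads per kb scaled to library depth) along parts of chromosomes 1, 2 and 13 in mm9 for the 5 libraries, with 1 scale for the Spt6 libraries and another for the 3 KDM6A libraries in each part. Spt6 density rises in myotubes over the chromosome 1 region that starts at 136185801 (11.1 times) and falls over the chromosome 13 region that starts at 21867801 (9.40 times lower).

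For KDM6A, the same comparison between stages gave fewer changed regions. Of 34837 regions, 497 were lower in myotubes and 27 were higher, with a median log2 ratio of -0.30. The region on chromosome 1 at 136186201 to 136190200, inside the strongest Spt6 gain, was 2.95 times higher in myotubes (2.24 to 3.94, 229 reads against 67), and the knockdown library had 61 reads there. KDM6A was 5.36 times lower in myotubes on chromosome 13 at 21870801 to 21872600 (3.76 to 7.82, 38 reads against 176, with 47 in the knockdown), inside a region of strong Spt6 loss. On chromosome 13 between 23624601 and 23856800, 11 of 28 regions were lower in myotubes.

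The first-ranked KDM6A gain was on chromosome 17 at 4626001 to 4626800, with 129 reads in myotubes against 2 in myoblasts (55.8 times higher, 15.1 to 465) and 3 in the knockdown. The remaining gained regions were small, on chromosome 11 at 24999401 to 25001200 (6.57 times, 2.58 to 21.4), chromosome 14 at 104736001 to 104736800 (4.45 times, 1.95 to 11.8) and chromosome 7 at 51729801 to 51730800 (4.21 times, 1.94 to 10.4), with 26, 11 and 9 knockdown reads. The remaining lost regions lay on chromosome 19 at 9062401 to 9072400 (2.96 times lower, 2.53 to 3.47, 307 knockdown reads), chromosome 1 at 39816001 to 39816600 (7.17 times, 2.76 to 23.6), chromosome 7 at 73520401 to 73521800 (5.78 times, 2.67 to 14.3) and chromosome 15 at 27411601 to 27412400 (5.62 times, 2.45 to 15.02). Those last 3 held 14, 24 and 26 knockdown reads. Scaling by the median of ratios moved the median from -0.30 to 0.00 and gave 197 higher and 72 lower regions.

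The knockdown library bears on how much of the KDM6A signal depends on KDM6A. Its control here is the KDM6A myoblast library, since the sample titles name no mock knockdown. With 1 library of each, a weaker immunoprecipitation and a loss of KDM6A cannot be told apart. Most of the enrichment of KDM6A regions was absent from the knockdown library: in the regions of the myoblast list the median density over flanks was 2.58 in the control (95% interval of the median 2.57 to 2.60, 25729 regions) and 1.22 after the knockdown (1.22 to 1.23). In the regions of the myotube list the control stood at 2.49 (2.46 to 2.51), the knockdown library at 1.29 (1.285 to 1.298) and the myotube library at 2.66 (2.63 to 2.69). Of 36285 regions, 20710 were lower after the knockdown and 168 higher, with a median log2 ratio of -1.06. On chromosome 3 at 96041201 to 96044600 KDM6A was 30.6 times lower after the knockdown (22.9 to 41.7, 49 reads against 765), and this region also held 643 reads of the Spt6 myoblast library.

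That region has one of the lowest ratios among those with Spt6 background, a set defined after the data were seen, of which 13389 were lower and 112 higher. This set holds fewer regions, and its median log2 ratio of -1.03 was near the -1.06 of all regions. Also among the lowest of that set were chromosome 1 at 56838801 to 56839400 and chromosome 5 at 60433801 to 60434400. Chromosome 11 at 103933801 to 103934600 and chromosome 13 at 9833401 to 9834000 were the others. In this order they held 380, 205, 324 and 103 control reads against 3, 4, 16 and 3 knockdown reads, and at most 9 reads of either Spt6 library. The lowest ratios over all regions were on chromosome 17 at 6814401 to 6840800 and 15152201 to 15171000, chromosome 3 at 92057401 to 92071000, chromosome 13 at 85266201 to 85267200 and chromosome 1 at 24618201 to 24623200. They held 857, 633, 600, 471 and 5262 control reads against 0, 0, 0, 0 and 19 knockdown reads, but at most 34 reads of either Spt6 library, so that reads of 3 of the 5 libraries are nearly absent there and no fold is given. Among the 19106 lower clear regions the lowest ratios were also in short regions with few Spt6 reads. The first of these was again chromosome 1 at 56838801 to 56839400, with 380 control reads, 3 knockdown reads and 3 and 6 Spt6 reads. Its Spt6 densities were 0.912 and 1.12 times those of its flanks, so its few Spt6 reads are near the local background. The highest ratios were on chromosome 15 at 14975201 to 14978400 (4.35 times higher after the knockdown, 2.44 to 8.43), 40285601 to 40289400 (3.57 times, 2.17 to 6.22), 35634601 to 35637400 (3.75 times, 2.14 to 7.10) and 11362401 to 11365000 (3.68 times, 2.09 to 6.97), and on chromosome 14 at 46822401 to 46827600 (3.16 times, 1.98 to 5.27). Scaling by the median of ratios, which assumes that most regions do not change and moves the median log2 ratio by 1.06, gave 3410 higher and 2490 lower regions. The knockdown at the level of RNA or protein was not analysed here.

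**Figure D3:**
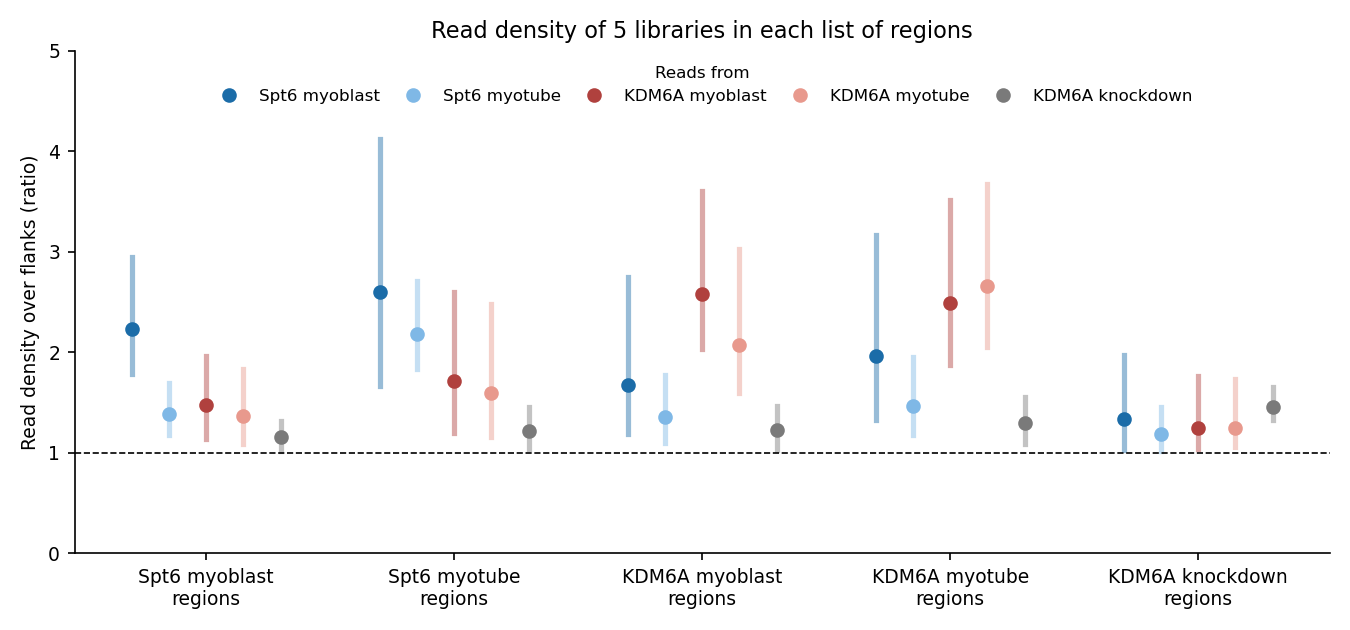
Read density in regions divided by that of their flanks (vertical axis, a ratio without unit) for each of the 5 region lists and 5 libraries, with points for medians and bars from the 25th to the 75th percentile. In the KDM6A myoblast regions the KDM6A myoblast library has a median of 2.58 and the knockdown library 1.22.

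Regions of the stages overlapped far above chance for both proteins. Of the Spt6 myotube regions 81.1% overlapped a Spt6 myoblast region (80.5% to 81.7%), against a mean of 11.7% after random shifts, and of the Spt6 myoblast regions 37.7% overlapped a myotube region (37.1% to 38.3%, shifted 6.54%). For KDM6A, 85.2% of the myotube regions overlapped a myoblast region (84.7% to 85.7%, shifted 11.02%) and 54.6% of the myoblast regions a myotube region (54.1% to 55.1%, shifted 7.33%). Of the KDM6A myoblast regions 5.20% overlapped a knockdown region (4.97% to 5.44%, shifted 2.26%). Across 508988 windows of 5 kb the Spearman correlation was 0.83 between the Spt6 libraries and 0.78 between the KDM6A libraries of the stages, with Pearson values of 0.79 and 0.93. Correlations of the knockdown library with the other 4 were between 0.59 and 0.68 (Spearman).

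Spt6 and KDM6A shared many regions within each stage. In myoblasts 51.4% of the Spt6 regions overlapped a KDM6A region (50.8% to 52.0%, shifted 12.9%), and 50.4% of the KDM6A regions overlapped a Spt6 region (49.9% to 51.0%, shifted 11.4%). In myotubes 49.7% of the Spt6 regions overlapped a KDM6A region (48.9% to 50.5%, shifted 7.46%) and 38.0% of the KDM6A regions a Spt6 region (37.4% to 38.7%, shifted 5.60%). Shared regions were more enriched. In myoblasts the KDM6A density over flanks was 2.89 in KDM6A regions that overlapped Spt6 (2.87 to 2.93) and 2.36 in those that did not (2.34 to 2.38), where the knockdown library gave 1.34 and 1.14. The Spt6 density was 2.60 in Spt6 regions that overlapped KDM6A (2.58 to 2.62) and 1.97 in the others (1.958 to 1.986), and the shared regions were wider, with medians of 6000 and 4600 bp. Window counts of Spt6 and KDM6A had a Spearman correlation of 0.73 in myoblasts and 0.65 in myotubes (Pearson 0.61 and 0.64), beside 0.65 and 0.68 for the Spt6 libraries with the knockdown.

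The final comparison asks whether Spt6 and KDM6A changed together during differentiation. In the 178 regions where Spt6 was higher in myotubes, KDM6A had a median log2 ratio of 0.13 (95% interval 0.06 to 0.18). The interval treats regions as independent, although some lay close together. Of the 178 regions, 118 (66.3%) lay above 0 against 28.3% of all regions. This median was above those of all 10000 random groups of the same size and read density, which ran from -0.29 to -0.05. The groups were not matched on the list a region came from. They were drawn from a pool that includes the KDM6A lists, whose merged regions had a median log2 ratio of -0.30. Regions picked by Spt6 need not hold KDM6A enrichment that could fall, so this rank alone does not show that KDM6A binding rose with Spt6. In the 5161 regions where Spt6 was lower the KDM6A median was -0.24 (-0.24 to -0.23), below all 1000 random groups (-0.20 to -0.17). Across all 36109 regions, however, the changes had a Spearman correlation of 0.02 and a Pearson correlation of 0.06. By chromosome the Spearman value ran from -0.07 to 0.17, and within 20 bins of read density it ran from -0.12 to 0.51 with a median of -0.026.

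Relative to all regions, the KDM6A difference in the regions with higher Spt6 was 0.31 on the log2 scale (0.24 to 0.37), and it was 0.19 over 155 regions when counts were scaled to the flanks. In the regions with lower Spt6 it was -0.05 (-0.06 to -0.04), and between -0.072 and -0.016 with scaling to the flanks or with either read length of the Spt6 myoblast library alone. KDM6A passed the 1.5-fold bound in 3 of the 178 regions, which are named after their values were seen. They lay on chromosome 1 at 136185801 to 136198800 (Spt6 8.16 times higher, 6.70 to 10.03; KDM6A 1.95 times, 1.61 to 2.38), chromosome 18 at 47523201 to 47531200 (1.94 times, 1.501 to 2.54, and 1.86 times, 1.51 to 2.30) and chromosome 2 at 76818001 to 76823800 (2.68 times, 1.89 to 3.88, and 2.64 times, 1.78 to 4.02). Their knockdown densities were 0.402, 0.494 and 0.448 RPKM (reads per kb, scaled to the depth of the library), against 0.616, 0.884 and 0.305 for KDM6A in its myoblast control and 1.203, 1.65 and 0.806 in myotubes. On chromosome 2 the knockdown was thus above its control. Both proteins were lower in 57 regions. Among these the region on chromosome 13 at 21867801 to 21873200 had myotube to myoblast ratios of 0.106 for Spt6 (0.0897 to 0.126) and 0.314 for KDM6A (0.237 to 0.411).

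**Figure D4:**
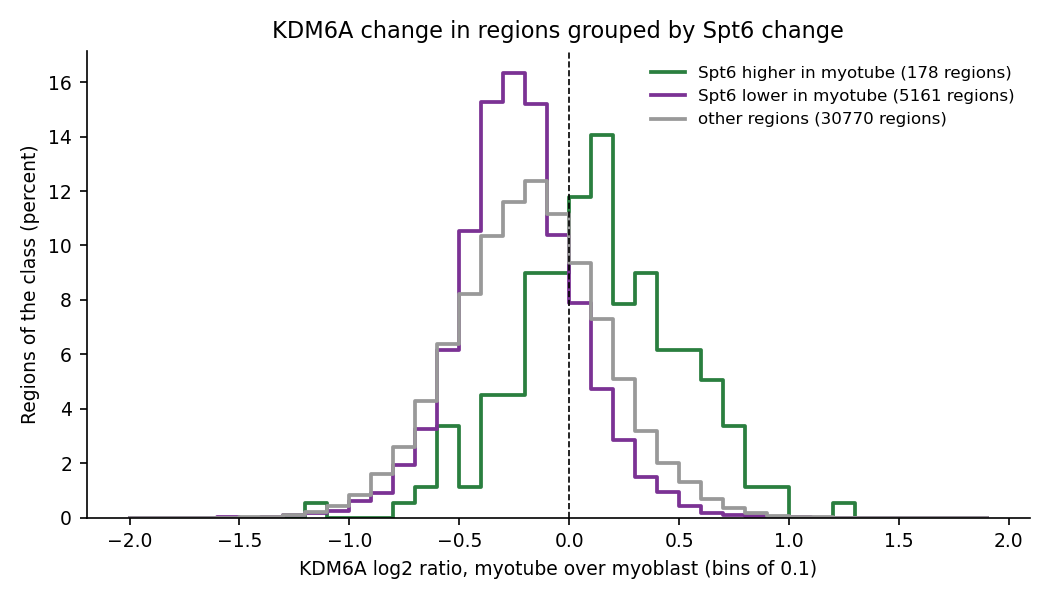
Distribution of the KDM6A log2 ratio between myotubes and myoblasts (horizontal axis, bins of 0.1; vertical axis, percent of the regions of each class) for regions where Spt6 was higher in myotubes (178), lower in myotubes (5161) or neither. The class with higher Spt6 is centred at 0.13 and that with lower Spt6 at -0.24.

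The knockdown list differed from the others in where its regions lay. Chromosome 15 held 1151 of its 4255 regions (27.1%, 25.7% to 28.4%) and chromosome 8 held 812 (19.1%, 17.9% to 20.3%), and on chromosome 8 most of them, 631, lay within the 21 Mb that start at 80 Mb. Together these chromosomes held 46.1% of the knockdown regions (44.6% to 47.6%) and between 11.4% and 15.1% of the other lists. Their background, measured outside all called regions in the 1 Mb windows around these regions in the Spt6 myotube library, was 1.24 times the genome median, against 1.13 around the other knockdown regions. These values were 1.23 and 1.27 in the Spt6 myoblast library, and 1.26 and 1.19, 1.298 and 1.11, and 1.32 and 1.12 in the KDM6A myoblast, myotube and knockdown libraries. The 168 regions that were higher after the knockdown included 83 on these chromosomes. In all 5 lists the densest region was on chromosome 17 at 39979801 to 39986000, or up to 39986600 in the KDM6A myotube list, with 60.5 RPKM for Spt6 in myoblasts, 39.0 for Spt6 in myotubes, 78.1 and 63.6 for KDM6A in myoblasts and myotubes, and 24.5 in the knockdown.

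**Figure D5:**
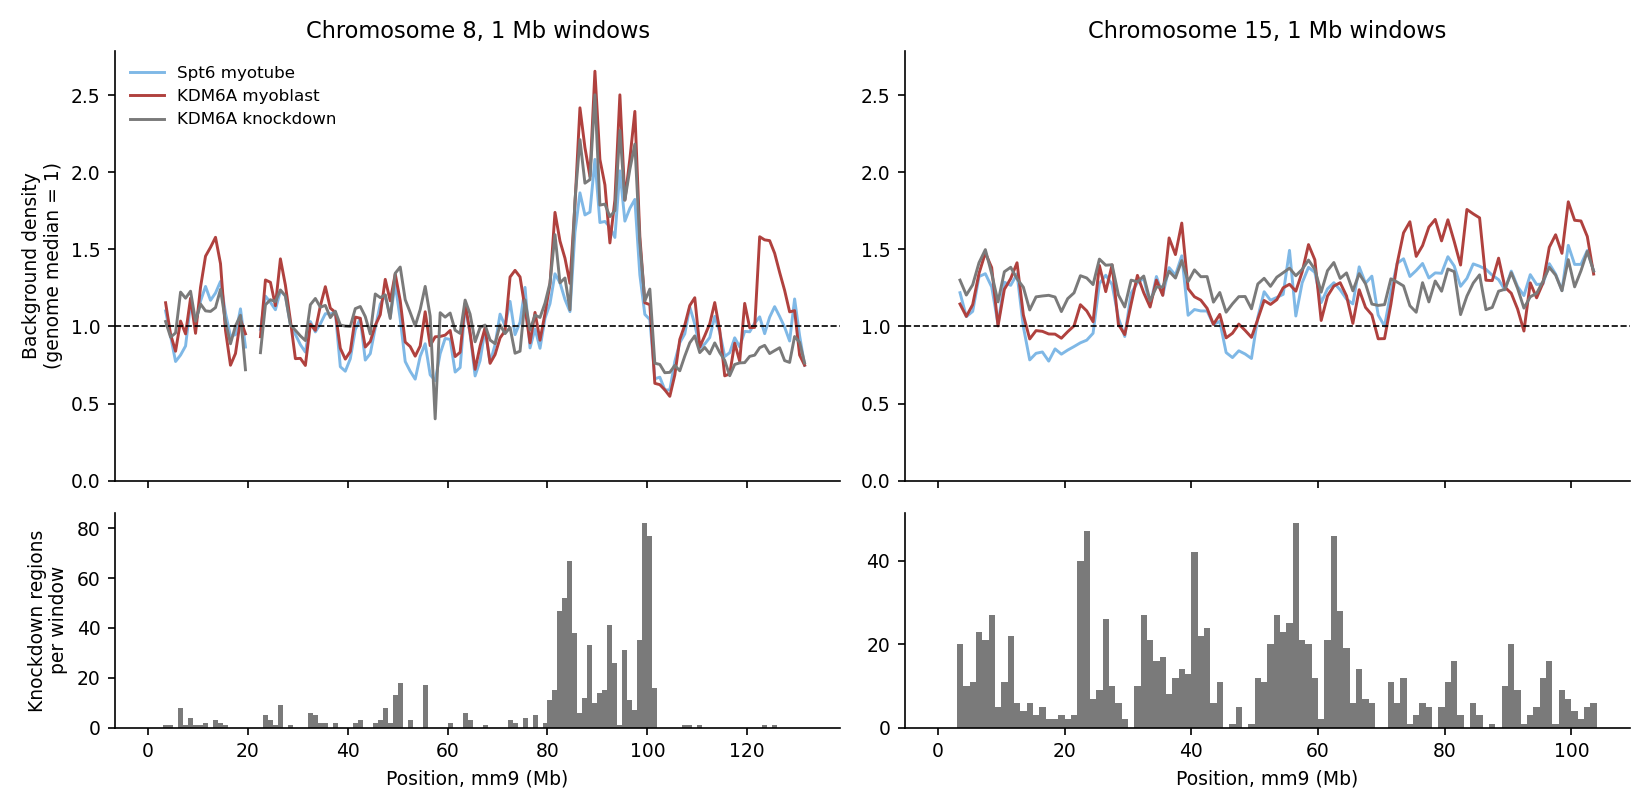
Background density of 1 Mb windows relative to the genome median, as lines for the Spt6 myotube, KDM6A myoblast and KDM6A knockdown libraries, and bars for the number of knockdown regions per window, along chromosomes 8 and 15 (Mb). Knockdown regions gather in the 21 Mb from 80 Mb on chromosome 8 (631 of 812) and along chromosome 15 (1151).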

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

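The tests of a uniform dilution, of mixed read lengths behind the smaller covered length and of depth and caller settings behind the narrower width were chosen only after the result was seen. For the other tests of Spt6 regions in this part the bounds were written before their result. Those tests still rest on calling at equal depth, on single read lengths or on density over flanks, which were chosen after the data were seen.

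The median width of the authors' regions changed in opposite directions with differentiation for the 2 proteins: the myotube to myoblast ratio was 0.56 for Spt6 and 1.31 for KDM6A, and this difference was not tested. With 1 calling method at equal depth the ratios were 0.963 and 0.947, so neither width change was kept.

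Spt6 regions were fewer, narrower and covered less of the genome in myotubes in the authors' lists. Sequencing depth as the cause of the smaller covered length is argued against by the depths themselves: 21963412 myotube reads were used against 13754270 myoblast reads. At equal depth the myotube regions covered 0.359 times the length of the myoblast regions. As only the myotube reads were thinned for this, that value adds nothing on depth. The mix of read lengths is argued against too, by calls at equal depth. Myoblast reads of 99 bases covered 76.6 Mb and those of 32 bases 39.0 Mb. These are 3.797 times the 10.3 Mb of myotube reads or more. For the narrower width the ratio at equal depth was 0.963. Depth alone would act the other way, as the myotube library was the deeper one. With this caller its median width was 2600 bp at 3813456 reads and 5200 bp at 13753241. Caller settings stay open as a cause. This caller gave 5400 bp for myoblast reads before and after dilution to the myotube enrichment, so it could hardly show a narrowing with lower enrichment. As it gave almost no narrowing, the 1.08-fold difference in median width between the read lengths decides nothing about the narrower width. A uniform dilution of signal as the whole difference is argued against by the 196 regions that were higher in myotubes, of which 33 were also higher with each read length of the myoblast library alone, although reads of 99 bases alone gave 39 and regions in both lists 13. A lower enrichment of the myotube immunoprecipitation and a loss of Spt6 binding in myotubes cannot be told apart for the smaller covered length: diluted myoblast reads covered 0.907 times the myotube length when matched over both Spt6 lists and 0.704 times when matched over the myoblast list, and each stage has 1 library.

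In the match strings of the Spt6 myotube reads, which entered no comparison, mismatches were concentrated at positions 37, 38, 40 and 41 of the read, in 49.6%, 52.3%, 50.1% and 36.2% of the reads. Only 34.8% of these reads had no mismatch, against 78.0% and 89.6% of the reads of 99 and 32 bases in the Spt6 myoblast library.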

How the results depend on the processing

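Scaling to the flanks, the clear regions, the regions with Spt6 background, single read lengths, calling at equal depth and the joint change with every alternative for it were chosen only after the result was seen. Of 204 alternatives to 48 results, 97 left the value within its error or 1.5-fold, 104 moved it and 3 reversed its direction. Some of the 97 could not have moved. The reads added do not enter the intervals behind the counts of higher and lower regions. The KDM6A files hold no repeated reads, so keeping repeated reads could not change their results. With 1 library per group, a difference in enrichment between immunoprecipitations and a change of binding enter the same counts. Ratios over genes, gene lists and their alternatives were not run, for want of an annotation of mm9.

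With the median of ratios the higher and lower regions were 1549 and 449 for Spt6, 197 and 72 for KDM6A between stages, and 3410 and 2490 for the knockdown, and the median log2 ratio of KDM6A between stages turned from -0.30 to 0.00012. That scaling sets the median near 0 by construction. Scaled to reads outside all regions, 98 were higher and 11258 lower for Spt6, and 35 were higher for the knockdown. Scaled to the flanks, 89 were higher and 3910 lower for Spt6, 246 were lower for KDM6A between stages, and 36 were higher and 11180 lower for the knockdown. A minimum of 100 reads, which leaves fewer regions, gave 78 higher for Spt6, 11 higher and 197 lower for KDM6A between stages, and 95 higher and 9407 lower for the knockdown. Regions in both lists only, again fewer, gave 13 higher and 2619 lower for Spt6, 8 and 81 for KDM6A between stages, and 0 and 247 for the knockdown. Reads of 99 bases alone gave 39 higher and reads of 32 bases alone 3406 lower regions for Spt6. In the regions with Spt6 background, a smaller set, 13389 were lower after the knockdown, with a median log2 ratio of -1.03 against -1.06 over all regions.

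When an overlap had to cover at least 50% of the region, shares fell to 17.8% (Spt6 myoblast regions in myotubes), 48.4% (KDM6A myoblast regions in myotubes), 4.49% (KDM6A myoblast regions in the knockdown), 25.2% (Spt6 myoblast regions in KDM6A) and 38.6% (Spt6 myotube regions in KDM6A). The upper part of each list by density gave 36.3%, 48.3%, 48.6% and 42.1% for the same overlaps without the knockdown. Lists of equal length gave 48.1%, 65.6%, 12.6%, 43.0% and 43.4%. Clear regions gave 53.6% for KDM6A between stages and 5.45% for the knockdown. With repeated reads kept, 27.8% of the Spt6 myoblast and 10.1% of the Spt6 myotube reads lay in regions.

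With 1 calling method at equal depth the myotube to myoblast ratios for Spt6 were 0.427 in number, 0.963 in width and 0.359 in covered length. For KDM6A they were 0.947 in width and 0.633 in covered length. The KDM6A width ratio was 1.31 in the authors' lists, so it counts as reversed, although the widths at equal depth were nearly the same. The Spearman correlation of Spt6 and KDM6A change reversed from 0.02 to a median of -0.026 within bins of density, which ran from -0.12 to 0.51. The KDM6A difference in regions with higher Spt6 was 0.19 when scaled to the flanks, and that in regions with lower Spt6 was -0.026 when scaled to the flanks, -0.072 with reads of 32 bases and -0.016 with reads of 99 bases. Except where the construction is named, the cause was not tested.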

Other observations

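The tests of copy number, of KDM6A binding left after the knockdown, of reads with several matches and of loss of KDM6A were all chosen only after the result was seen, as were the counts of regions in which both proteins changed.

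Spt6 and KDM6A were both lower in myotubes in regions of several chromosomes. Some of these regions lay close together, on chromosome 13 within 21806601 to 21873200 and within 23642201 to 23857200. Others did so on chromosome 3 within 96022001 to 96053600. Whether these regions cluster beyond chance was not tested. On chromosome 13 at 21867801 to 21873200 the myotube to myoblast ratio was 0.106 for Spt6 (0.0897 to 0.126) and 0.314 for KDM6A (0.237 to 0.411), and at 23646001 to 23649000 the ratios were 0.208 (0.182 to 0.237) and 0.420 (0.345 to 0.510). On chromosome 17 at 23799201 to 23815200 they were 0.209 (0.189 to 0.230) and 0.435 (0.382 to 0.493), and on chromosome 4 at 135678601 to 135679800 they were 0.313 (0.148 to 0.632) and 0.247 (0.109 to 0.510). On chromosome 5 at 143655201 to 143674600 they were 0.160 (0.148 to 0.173) and 0.490 (0.441 to 0.545), and on chromosome 3 at 96022001 to 96028000 they were 0.319 (0.278 to 0.365) and 0.456 (0.379 to 0.548). Of the 180 jointly measured regions in which KDM6A was lower in myotubes, Spt6 was lower in 57, against 14.3% of all jointly measured regions, but its log2 ratio was below 0 in 143 of them, against 80.5% of all regions, and its median was -0.52 against -0.49. Of the 13 in which KDM6A was higher, 11 had a Spt6 log2 ratio above 0 and 3 passed the 1.5-fold bound. The direction of these counts depends on the scaling of each protein, and no random groups were drawn for them.

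Some of the densest regions were dense in all 5 libraries and with both antibodies, so their density in the knockdown library need not be KDM6A left there. On chromosome 9 at 35112601 to 35113400 the densities were 40.5 RPKM for KDM6A in myoblasts, 35.6 in myotubes, 15.9 in the knockdown, and 38.4 and 26.4 for Spt6 in myoblasts and myotubes. By contrast, the region on chromosome 13 at 23646601 to 23649000, among the densest for Spt6 in myoblasts at 27.5, had 5.62 for Spt6 in myotubes, 6.74 and 2.73 for KDM6A in myoblasts and myotubes and 0.619 in the knockdown. The longest Spt6 region in myoblasts ran over 232.4 kb of chromosome 16, from 92597401 to 92829800, and the longest in myotubes over 86.8 kb of chromosome 15, from 77586401 to 77673200. Chromosome 7 held 5 of the knockdown regions (0.118%, 0.0502% to 0.275%), against 3.14% to 4.79% of the regions of the other 4 lists.

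The knockdown regions were concentrated on chromosomes 15 and 8. KDM6A binding left after the knockdown is argued against only as the main source of those on these chromosomes. The KDM6A myoblast library had a median density of 1.16 times the flanks in them, below the 1.399 of the knockdown library. The regions were picked in the knockdown library, which favours it, so binding left in part of them stays open. Of all knockdown regions 35.1% overlapped a KDM6A myoblast region, against 14.6% after random shifts. In those on the other chromosomes the medians were 1.41 for KDM6A and 1.58 for Spt6 in myoblasts. Whether extra copies of chromosome segments lie behind the concentration on chromosomes 15 and 8 stays open. The background density around the regions there was 1.24 times the genome median in the Spt6 myotube library, against 1.13 around the other knockdown regions. This density was higher in the 3 KDM6A libraries too (1.26 against 1.19, 1.298 against 1.11 and 1.32 against 1.12), but 1.23 against 1.27 in the Spt6 myoblast library. With each 1 Mb window counted once the 5 libraries gave 1.202 to 1.254, against 0.998 to 1.016 for the other autosomes, whose windows were not picked for holding knockdown regions, and for the 631 regions within 21 Mb from 80 Mb on chromosome 8 they gave 1.28 (both Spt6 libraries), 1.54, 1.57 and 1.31. In that stretch the Spt6 myotube windows that start at 85 to 97 Mb stood at 1.58 to 2.08, but those at 99 and 100 Mb, with 82 and 77 knockdown regions, at 1.08 and 1.04, and copy number was not measured and the bound of this test was set with the profile in view.

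Many KDM6A reads fell in 1 kb windows that held no knockdown read, in 9434 windows with at least 10 KDM6A myoblast reads. These windows cannot show whether KDM6A was lost, since Spt6 reads, from another antibody, are scarce there too. The Spt6 myotube library had only 17.1% of its mean density in them, so missing knockdown reads need not mean a loss of KDM6A. The same value is consistent with reads of several genomic matches having been kept in the KDM6A myoblast and myotube files and removed from the others. Of these windows 53.7% held no Spt6 myotube read, against 0.167% of the 621949 windows that did hold knockdown reads, and the KDM6A myotube library stood at 235% of its mean in them. The knockdown counts are therefore given also for regions with Spt6 background. That set still holds short regions with many control reads and few knockdown and Spt6 reads. An example is chromosome 1 at 56838801 to 56839400, with 380 control reads against 3 knockdown reads.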
